A study of Drosophila melanogaster with 2 samples.

How the data were processed

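The 2 embryo samples analysed were biological replicates 1 and 3 of 1 MESR4-GFP group. Per the labels, chromatin was fragmented by sonication to 200 to 800 bp and the assay was transcription factor ChIP-seq on pooled male and female embryos. The free text of the labels calls both samples input controls. The antibody label names MESR4, and the listing deposited with each sample shows the replicate lists to have been called against a separate control alignment, so both were taken as MESR4 immunoprecipitates. The labels do not say which antibody recognised the fusion protein.

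Per the listing deposited with each sample, peaks and background regions were called for each replicate against 1 shared control alignment and for both replicates together. A further list kept peaks that passed a threshold on the irreproducible discovery rate (IDR), which compares peak ranks between replicates. The aligner, the peak caller, the IDR threshold, the number of reads and the treatment of reads that map to several places were not given in the sources used here. The deposited signal value of each peak is the authors' measure of enrichment on a scale set per list, so signals were compared within a list and lists were compared by rank. The lists also hold a deposited −log10 q value per peak, which repeats its maximum at the strongest peaks and was not used for ranking. The thresholded list was checked against the list of both replicates, and all its 6415 summits and signals were found there as the 6415 highest. Some regions hold more than 1 summit (818 in the thresholded list), and each summit counted separately.

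Coordinates were those of the deposited lists in dm6, given from 1 here. Genes came from Ensembl release 115 and sequence from the release 6 genome, and all peak ends lay within its arm lengths. Analyses used arms 2L, 2R, 3L, 3R, 4 and X. The tandem histone cluster (2L, 21416953 to 21541681, 111 genes) was left out of gene counts because its copies share reads, and no list had a summit there. This left 13834 protein-coding genes.

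A promoter summit was a summit within 500 bp of any annotated TSS, and other summits went to 5' UTR, coding exon, 3' UTR, non-coding exon, intron or intergenic sequence, in that order. A gene had a promoter peak when a thresholded summit lay within 500 bp of any of its TSSs, and its signal was that of the strongest such summit. One summit can therefore count for neighbouring genes. Random expectation came from 10000 seeded placements of the same number of summits per arm, leaving out N bases, and replicate overlap from 1000 placements. Shares have Clopper-Pearson 95% intervals, which treat genes or summits as independent and do not cover variation between replicates. Gene lists and chromosomes were compared with two-sided Fisher's exact tests and Benjamini-Hochberg adjustment at 0.05, within each family of tests. Printed log2 odds ratios of lists had 0.5 added to each cell. Signals were compared by permutation tests of medians with 100000 permutations for promoter against distal summits and 10000 for gene lists, whose comparison was added after the data were seen. Motifs were matched on both strands within 100 bp of the summit, against 1 flank per summit centred 500 bp away, on alternating sides by rank (exact McNemar test), and against 201 bp at the TSS of promoters without a peak (Fisher's exact test). The TSS of a gene was that of its canonical transcript for these windows, for GC content and for initiator searches. Summit offsets used genes without another gene's TSS within 1000 bp and bootstrap intervals of 2000 draws. Neighbouring TSSs here and below were those of the protein-coding genes counted, so genes near a non-coding gene's TSS were kept. Offsets were measured after the data were seen.

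The 23 gene lists, the 17 motifs and most tests and alternatives were fixed before the data were examined. Lists were written from textbook knowledge of fly genetics or as symbol patterns for gene families, and 20 older symbols were matched to current ones. Genes were named by a fixed rule. It took the nearest protein-coding gene of the 20 strongest peaks, MESR4, roX1 and roX2, and up to 4 members with the strongest promoter peak of each list past the threshold. Genes named outside this rule were chosen after their values were seen. A list member and the strongest summit within 500 bp of a MESR4 TSS, which the rule takes, are not reported here.

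The alternatives were windows of 250 and 1000 bp, the 3207 summits with the highest signal as a stricter threshold, the top 6415 summits of each replicate alone, other overlap rules, tests stratified by TSS number, and genes without a neighbouring TSS within 1000 bp. Alternatives added after the data were seen were merged summits, protein-coding TSSs alone, stratification by 5 bins of GC content around the TSS, counting a summit for the nearest TSS alone, and TSS-centred motif windows. No comparison between groups or paired analysis was possible with 1 group. The promoter share, gene list, summit motif, overlap and signal tests were tested on simulated data, while offsets, stratified tests and the Fisher tests of motifs were not. In 100 simulations of the gene list test with 13945 genes, the histone cluster included, and 20 lists of 40 genes, 99.0% of lists raised to 80.0% or lowered to 10.0% from 42.0% were called in the right direction, and 1.13% of unchanged lists were called. Genes were drawn at random with independent peaks, so these rates do not apply to smaller lists, smaller differences or neighbouring genes that share summits. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.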

Results

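Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map MESR4, a nuclear protein with PHD and zinc fingers named after a misexpression screen for suppressors of Ras. The flies carried MESR4 with green fluorescent protein (GFP) at its C terminus, and the material was mixed-sex whole embryos collected between 0 and 24 h of development. The series had 1 group with 2 biological replicates, numbered 1 and 3, and 4 peak lists were analysed. Each replicate list and the list from both replicates together held 30000 summits. The thresholded list held 6415 summits in 5534 regions with a median width of 524 bp. Signal values ran from 176.1 to 3171 in the thresholded list, with a median of 378.7. Read depth was not given in the sources used here, so intervals below cover counting of genes or summits and not read sampling. Thresholded summits lay on all 6 main chromosome arms of the dm6 genome, at 44.7 per Mb on 3L, 47.5 on X, 47.6 on 3R, 49.2 on 2L, 51.0 on 2R and 57.8 on 4.

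The 2 replicates placed their strongest peaks at largely the same positions. Of the 6415 strongest summits of replicate 1, 5834 were in a region that shared at least 1 bp with the region of a summit among the 6415 strongest of replicate 3 (90.9%, Clopper-Pearson 95% interval 90.2 to 91.6). Random placement of replicate 3's regions on the same arms gave a mean of 4.29% and at most 5.30% (permutation p = 0.001, the smallest value 1000 placements can give). In the other direction 5403 summits of replicate 3 (84.2%) were in shared regions, and the regions of 98.6% met some region in the full list of replicate 1. A region with several summits counts once per summit in these shares. Across the 6019 thresholded peaks found in both replicates, signal ranks were correlated (Spearman 0.741, Pearson 0.696 on log10 signal), a description across peaks, which are not independent replicates. Summits were placed less exactly than regions, since 72.7% of replicate 1's summits lay within 100 bp of one in replicate 3.

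MESR4 occupancy was concentrated at promoters. Of the 6415 summits, 5825 lay within 500 bp of an annotated transcription start site (TSS), or 90.8% (interval 90.1 to 91.5), against 13.6% ± 0.423 (SD over 10000 random placements on the same arms), a ratio of 6.68 (permutation p = 0.0001, one-sided, the smallest value possible). Outside promoters, introns held 394 summits (6.14%, random 39.5%) and intergenic sequence 142 (2.21%, random 27.1%). Coding exons held 13 summits, 3' UTRs 19, non-coding exons 12 and 5' UTRs 10, and each of these 6 classes was below random placement (adjusted permutation p = 0.0002 each, two-sided), as the promoter share leaves few summits for them. With a 250 bp window the direction turned for 5' UTRs, at 2.40% against 1.33% at random (adjusted permutation p = 0.0002). The 590 summits outside promoters lay a median of 1772 bp from the nearest TSS and 100 were more than 5000 bp away. They were weaker than the promoter summits, with a median signal of 238.2 against 401.7 (difference of 0.227 in median log10 signal, two-sided permutation p = 1e-05, the smallest value 100000 permutations can give).

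**Figure D1:**
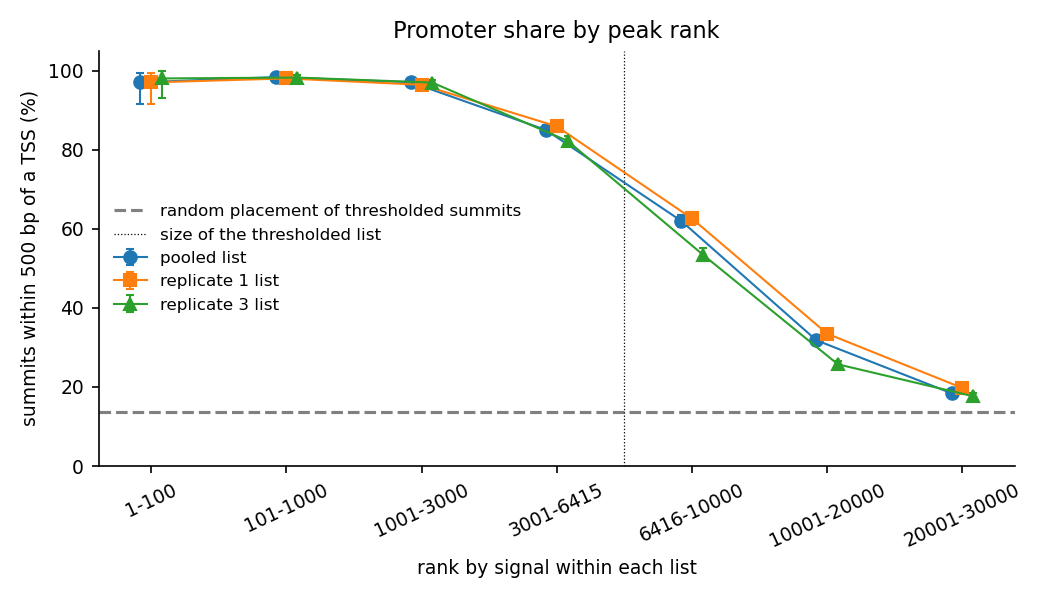
Share of summits within 500 bp of a TSS (y axis, percent) by rank of signal within the list (x axis), for the list of both replicates together and for each replicate list, with Clopper-Pearson 95% intervals. The dashed line is the mean of random placements of the thresholded summits (13.6%), the dotted line marks the size of the thresholded list, and the share in the list of both replicates falls from 97.0% in the first 100 summits to 18.4% in ranks 20001 to 30000.

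The MESR4 gene (FBgn0034240, chromosome 2R, 17547769 to 17556289, plus strand) had a summit at 17547628, 141 bp upstream of its first TSS, with a signal of 295.4. It was not the strongest summit within 500 bp of a MESR4 TSS, so this value does not measure the strength of the promoter peak. Its position was not shared by both replicates. Replicate 1 had a summit close by, at 17547654 and upstream of the first TSS. In replicate 3 the summit nearest to that TSS lay at 17547907, 138 bp downstream. A position upstream of a TSS does not by itself assign a peak to that gene alone.

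The strongest peaks of the list were at genes of the ribosome. Among the 20 strongest peaks with a protein-coding TSS within 500 bp, 13 were at cytosolic ribosomal protein genes, and the signals of the 20 ranged from 1916 to 3171. RpL30 (chromosome 2L, 19008031 to 19009306, minus strand) ranked first in the thresholded list and in each replicate. Its summit was at 19009191 in an intron, 46 bp downstream of the nearest of the gene's annotated TSSs. RpL24 had a signal of 2609, RpS4 of 2585, RpL27A of 2292, RpS24 of 2078, RpL13A of 2067 and RpL14 of 2046. RpS3A (2018), RpL8 (2007), RpS27A (2006, equally near the divergent gene's TSS), RpL6 (1978), RpS18 (1938) and RpL19 (1916) made up the rest of the ribosomal group. The other 7 were Non1 (2275), VhaSFD (2136), a subunit of the vacuolar ATPase, His3.3B (2034), a gene for the replacement histone H3.3, CG12054 (2009), ATPsynC (1997), the c subunit of mitochondrial ATP synthase, CG2519 (1942) and RhoGAP92B (1930). The 20 peaks ranked no lower than 33 in replicate 1 and 169 in replicate 3, and 19 of the 20 summits lay downstream of the nearest TSS.

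Less than 1 protein-coding gene in 2 carried a promoter peak. A summit lay within 500 bp of a TSS in 5889 of 13834 genes, or 42.6% (interval 41.7 to 43.4). On the small chromosome 4, which is largely packaged as heterochromatin, 49 of 80 genes had one (61.3%, interval 49.7 to 71.9) against 42.1% on the other autosomes (adjusted exact p = 0.00123, Fisher's test). On X the share was 44.5% against 42.2% on autosomes (adjusted exact p = 0.0481, log2 odds ratio 0.13), and this call was lost with a 250 bp window (adjusted exact p = 0.0944) and without replicate 3 (0.053), while the log2 odds ratio was -0.13 in the stronger 3207 summits. Counting each summit for the nearest TSS alone left 36.01% of genes, and the stronger 3207 summits left 27.4%. Of the genes without a neighbouring TSS within 1000 bp, 1956 of 7933 had a promoter peak, so genes with such a neighbour carried one more often.

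Gene groups split sharply by function. Of 23 gene lists, 10 had a promoter peak more often than other protein-coding genes, 8 less often and 5 did not pass the test (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over the 23 lists). Genes of protein synthesis and energy supply stood high. Cytosolic ribosomal protein genes carried a promoter peak in 85 of 92 cases (92.4%, adjusted exact p = 3.2e-23), led by RpL30, RpL24, RpS4 and RpL27A. Mitochondrial ribosomal protein genes did in 70 of 73 (95.9%, adjusted exact p = 6.1e-22), with the strongest peaks at mRpS23 (1536), mRpS16 (1314), mRpS11 (1089) and mRpS10 (947.1). Of these 4, the summit lay nearer to another gene's TSS at mRpS23, mRpS16 and mRpS10. Counting each summit for the nearest TSS alone left 54 of 73 mitochondrial ribosomal protein genes with a promoter peak (74.0%). The log2 odds ratio was then 2.32 against 4.78, and the call held (adjusted exact p = 2.2e-10). The same rule left 82 of 92 cytosolic ribosomal protein genes (89.1%). Among mitochondrial ribosomal protein genes without a neighbouring TSS within 1000 bp, 13 of 13 had a promoter peak. Oxidative phosphorylation genes had one in 63 of 84 cases (75%, adjusted exact p = 1.1e-08), among them ATPsynC, ATPsynF (1528), COX7A (1284) and ATPsynbeta (1274). Proteasome subunit genes had one in 33 of 48 (68.8%, adjusted exact p = 0.00056), with Prosbeta7 (831.2), Rpt5 (813.9), Rpn13 (760.5) and Rpn1 (754.4) highest. Among genes without a neighbouring TSS within 1000 bp the proteasome list kept a similar log2 odds ratio, 1.36 (10 of 22 genes) against 1.55, and lost its call with fewer genes (adjusted exact p = 0.0615).

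Chromatin, growth-control and some signalling genes were also high. Polycomb and Trithorax group genes, which keep developmental genes off or on, carried a promoter peak in 31 of 35 cases (88.6%, adjusted exact p = 8.7e-08), with trx (1104), Jarid2 (1099), kis (1091) and ph-p (1086) highest. The same held for 18 of 20 insulator and architectural protein genes (adjusted exact p = 3.2e-05), among them Chro (1020), row (908.4), mod(mdg4) (845.9) and Clamp (820.3). Cell cycle and DNA replication genes had one in 38 of 46 cases (82.6%, adjusted exact p = 1.1e-07). Their strongest were dup (1821) and Dp (935.6), both with the summit nearer to a neighbour's TSS, Bub1 (733.5) and geminin (651.3). Among the stronger 3207 summits this call was lost (adjusted exact p = 0.234). Insulin and TOR signalling genes had one in 18 of 24 cases (75%, adjusted exact p = 0.0023), among them S6k (1517), Pi3K21B (1161) and Lnk (1065). Wnt, Hedgehog and Dpp signalling genes had one in 24 of 38 (63.2%, adjusted exact p = 0.0175), including Axn (1009), pan (832.7), fu (815.3) and Su(fu) (796.9). The last of these summits was nearer to the TSS of Arp1. All 10 dosage compensation genes carried one (adjusted exact p = 0.00034), among them msl-1 (887.2), msl-3 (750.1) and mle (743.0). The roX RNAs, the non-coding partners of that complex on X, also had promoter peaks, at signals of 424.1 for roX1 and 348.3 for roX2.

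Developmental patterning genes and late, tissue-restricted genes were low. None of the 8 Hox genes carried a promoter peak (interval 0 to 36.9%, adjusted exact p = 0.0313), and this call was lost among the stronger 3207 summits (adjusted exact p = 0.159) and among genes without a neighbouring TSS (0.248), and under 2 alternatives added later. Among segmentation genes 3 of 30 had one (adjusted exact p = 0.00028), namely ci (268.4), nkd (251.5) and ptc (177.3). All 3 are also members of the Wnt, Hedgehog and Dpp signalling list, which was high, so a low and a high list share genes. The segmentation call was lost among genes without a neighbouring TSS (adjusted exact p = 0.11), with a log2 odds ratio of -1.37 against -2.55. The list still had 3 of 30 genes, while a smaller share of all genes in that set had a promoter peak (1956 of 7933). Neural transcription factor and fate genes had one in 2 of 35 cases (adjusted exact p = 6.2e-06), elav (458.0) and pros (178.2), with 6 of 35 without replicate 1 (adjusted exact p = 0.0023) and 1 of 35 without replicate 3. Mesoderm and muscle genes had one in 3 of 33 (adjusted exact p = 0.00011), Mef2 (600.7), Tm1 (465.6) and tin (329.4). Chemosensory genes had one in 3 of 230 cases (1.30%, adjusted exact p = 2.6e-49), Ir60e, Gr63a and Obp99b, with 5 without replicate 3. Cuticle protein genes had none in 117 (upper bound 3.10%, adjusted exact p = 1.1e-27) and chorion and vitelline membrane genes none in 14 (adjusted exact p = 0.00084). The chorion call was lost among genes without a neighbouring TSS, none of 11 having a peak (adjusted exact p = 0.103). Seminal fluid genes had one in 3 of 47 (adjusted exact p = 1.4e-07), Sfp26Ad, Acp98AB and Sfp24F, and at all 3 the summit was nearer to another gene's TSS, as it was at Ir60e and Gr63a.

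In 5 groups, 41.7% to 55.3% of genes had a promoter peak and the difference from other genes did not pass the test. These were Ras, EGFR and FGFR signalling (22 of 41), Notch signalling (16 of 29), lipid metabolism (21 of 38), germline and piRNA (12 of 27) and heat shock and chaperones (10 of 24). Their adjusted exact p values were 0.181, 0.208, 0.168, 0.886 and 1. The Ras list passed without replicate 1 (adjusted exact p = 0.00036) and among genes without a neighbouring TSS (0.0471). Of the heat shock genes without a peak, the Hsp70 copies are nearly identical, so reads there are uncertain.

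**Figure D2:**
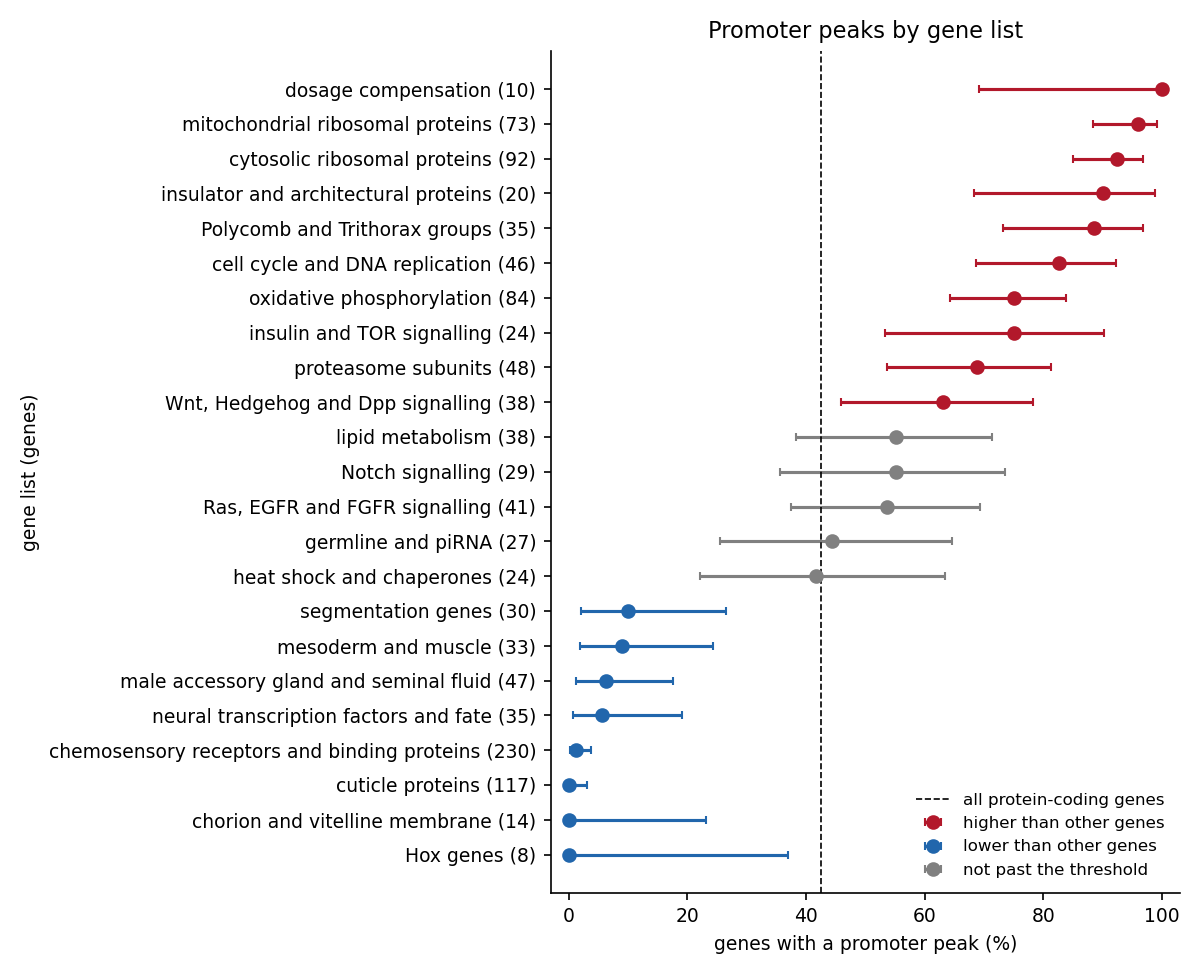
Share of genes with a promoter peak (x axis, percent) in each of 23 gene lists (y axis, number of genes in parentheses), with Clopper-Pearson 95% intervals. Red lists were higher and blue lists lower than other protein-coding genes after adjustment, grey lists did not pass, and the dashed line is the share in all 13834 genes (42.6%).

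Signal at bound promoters was highest for the ribosome. Cytosolic ribosomal protein promoters had a median signal of 1331 (85 genes) against 464.1 at other bound genes, a ratio of 2.87 (adjusted permutation p = 0.0007). Oxidative phosphorylation promoters had a median of 658.6 (63 genes), a ratio of 1.41 (adjusted permutation p = 0.0007). Mitochondrial ribosomal protein promoters had a median of 457.8 and a ratio of 0.978 (adjusted permutation p = 0.833). None of the other lists with at least 5 bound genes passed this test, the lowest adjusted permutation p being 0.149 for Polycomb and Trithorax genes and for Ras signalling genes.

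**Figure D3:**
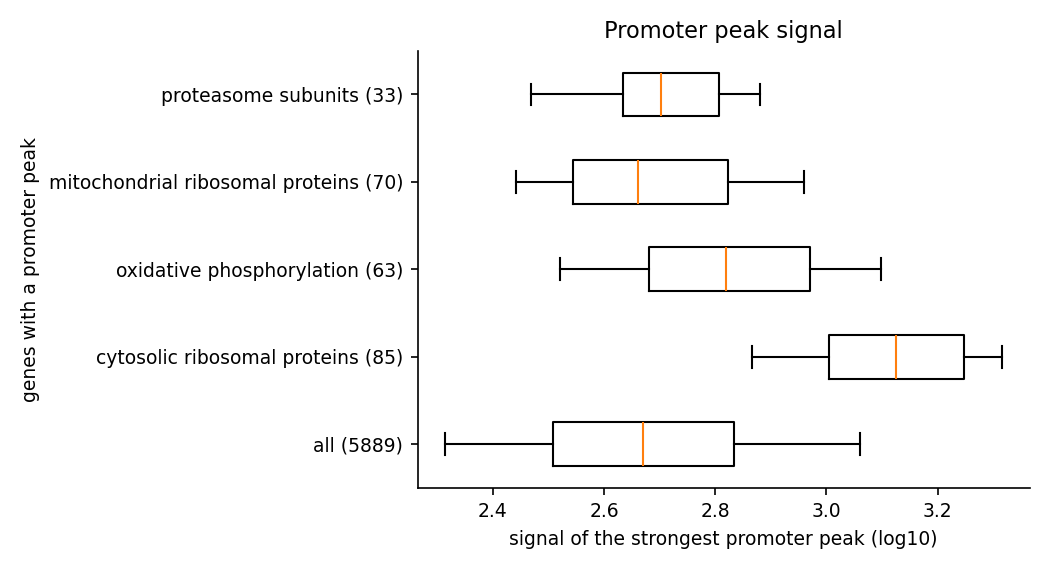
Signal of the strongest promoter peak per gene (x axis, log10 of the deposited signal value) for all bound protein-coding genes and 4 gene lists (y axis, number of genes in parentheses). Boxes span the quartiles with the median as a line and whiskers reach the 5th and 95th percentiles, and the cytosolic ribosomal protein genes (median 1331) sit to the right of the other groups.

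Within bound promoters the summit sat just inside the gene. At 1956 bound genes without a neighbouring TSS within 1000 bp, the median summit was 80 bp downstream of the TSS (bootstrap 95% interval 74 to 84) and 80.7% of summits were downstream. The 29 cytosolic ribosomal protein genes in this set had the same median, 80 bp. The offset was 54 bp in replicate 3 alone and 95 bp in replicate 1 alone. Both values lie outside the bootstrap interval, which does not cover variation between replicates.

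**Figure D4:**
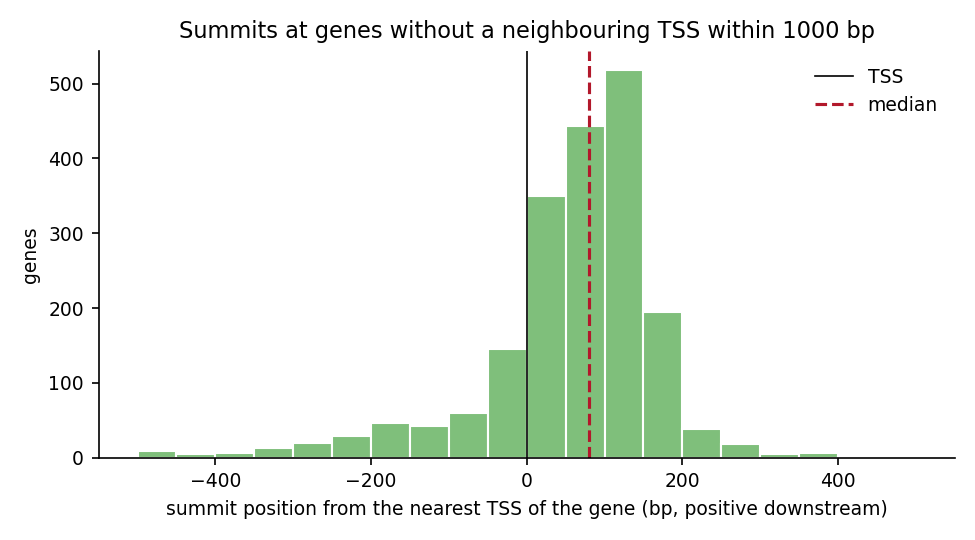
Number of genes (y axis) by position of the strongest promoter summit relative to the gene's nearest TSS (x axis, bp, positive downstream), in bins of 50 bp, for 1956 genes without a neighbouring TSS within 1000 bp. The dashed line is the median, 80 bp downstream.

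Few short RNA genes had a summit near the annotated 5' end, and whether that end is a promoter was not examined. A summit lay within 500 bp of the 5' end of 5 of 290 tRNA genes (1.72%), 2 of 32 snRNA genes (6.25%), 36 of 269 snoRNA genes (13.4%) and none of 99 rRNA genes (upper bound 3.66%). Each class was below protein-coding genes (adjusted exact p = 2.2e-59 for tRNA, 7.3e-06 for snRNA, 2.3e-24 for snoRNA and 2.7e-24 for rRNA). Without replicate 1 the counts were 11 for tRNA (3.79%) and 5 for snRNA (15.6%), and without replicate 3 they were 8 (2.76%) and 1 (3.13%), each still below protein-coding genes. Away from protein-coding TSSs, none of 258 tRNA genes had a summit, while 2 of 29 snRNA genes (6.90%) and 20 of 240 snoRNA genes (8.33%) did. The 2 snRNA genes, named after their values were seen, were snRNA:U1:95Ca and snRNA:7SKa. Repeated copies of tRNA, rRNA and snRNA genes can lose reads that map to several places, and how such reads were treated was not given in the sources used here.

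Promoters with a peak differed in sequence from promoters without one. Around summits, 9 of 17 motifs were more frequent than in flanks 400 to 600 bp away, 4 were less frequent and 4 did not pass (exact McNemar test, adjusted over 34 tests). The largest log2 ratio was that of Motif 1, bound by the factor M1BP, found at 5.44% of summits and 1.496% of flanks (adjusted exact p = 1.7e-34). The DNA replication-related element (DRE) was at 3.98% against 2.01% and Ohler motif 7 at 5.97% against 3.06%. Within 50 bp of the summit DRE was at 1.54% against 1.12%, and its call was lost (adjusted exact p = 0.0632). With windows at the TSS in both groups, a comparison chosen after the data were seen because summits lay downstream, the contrasts of Motif 1, DRE and the GAGA element widened, those of the initiator and the TATA box narrowed, and those of the CA repeat and the A tract turned in direction, neither past the threshold. Motif 1 was in 14.0% of 5889 promoters with a peak and 1.03% of 7945 without one, and DRE in 15.3% against 1.83% (log2 odds ratios 3.97 and 3.28). The initiator was in 18.7% against 37.5%, the TATA box in 24.1% against 32.1% and the GAGA element in 18.1% against 25.8%. With windows at summits for bound promoters, as first planned, Motif 1 was at 5.92% against 1.03% and DRE at 4.24% against 1.83%. Among the stronger 3207 summits, the DRE, DRE core, Ohler motif 6 and BEAF core contrasts of the planned comparison turned in direction. None was past the threshold. The 10048 promoters then counted as without a peak took in those with weaker thresholded peaks. DRE changed mainly in that group, from 1.83% to 4.23%, and from 4.24% to 3.82% at promoters with a peak. The windows also differed, at summits for promoters with a peak and at the TSS for those without. With windows at the TSS in both groups, DRE was in 15.3% of the 5889 promoters with a peak. These turns therefore do not show that strong peaks lack the motifs.

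**Figure D5:**
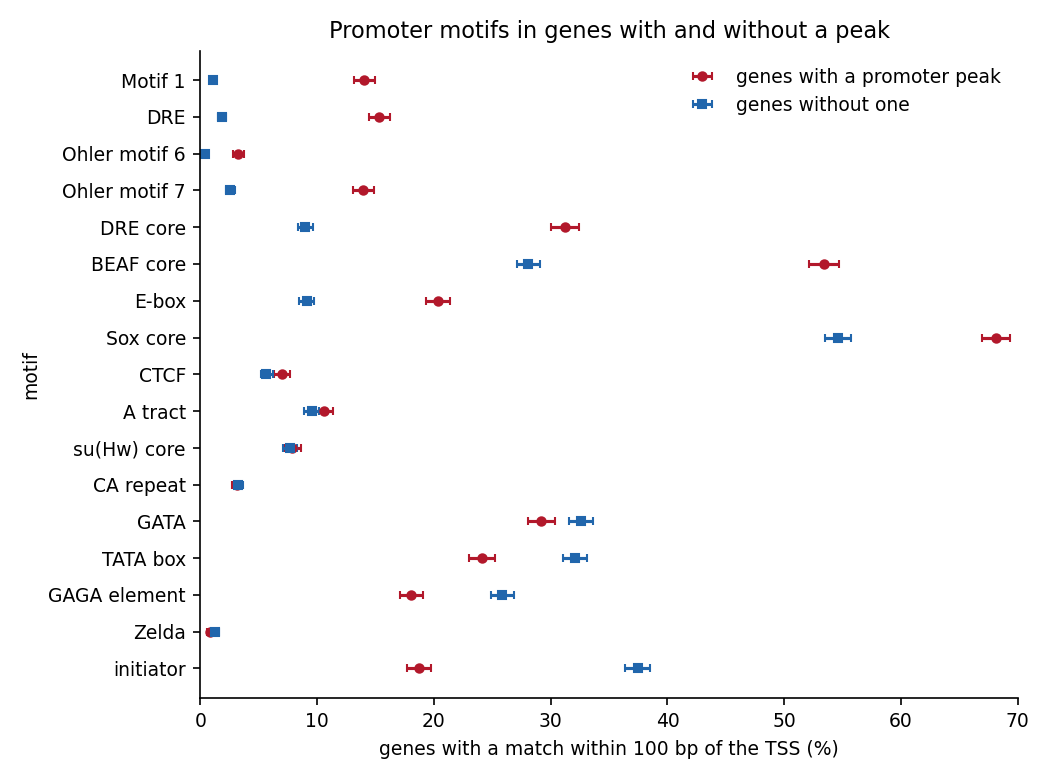
Share of genes with a motif match within 100 bp of the TSS (x axis, percent) for 17 motifs (y axis) in 5889 genes with a promoter peak and 7945 without one, with Clopper-Pearson 95% intervals. Motif 1 and DRE stand far higher in genes with a peak (14.0% against 1.03% and 15.3% against 1.83%), and the initiator lower (18.7% against 37.5%).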

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

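The tRNA comparisons and the signal comparison between gene lists were chosen after the results were seen, and the GC stratification was added then too. Promoter signal continued below the authors' threshold, in summits of the list of both replicates that the gene list and motif comparisons above did not use. Of the 23585 summits of the list of both replicates that fell below the threshold, 30.7% lay within 500 bp of a TSS, above the 13.6% of random placement. Of those 23585, 1699 shared a top peak with both replicates and 1619 of these lay at promoters.

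The split of gene lists into often and rarely bound groups was weighed against 3 technical explanations. Stratified by the number of annotated TSSs, 18 of the 18 lists past the threshold kept their call and direction. Among genes without another protein-coding TSS within 1000 bp, which removes peaks shared between protein-coding genes, 14 kept it. The lost calls were proteasome, Hox, segmentation and chorion genes. Stratified by GC content, 17 kept it. These values argue against TSS number, shared peaks or GC content as the whole cause, while open chromatin and transcription level stay open because neither was analysed here, and with 1 group no biological explanation was tested.

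The stronger peaks of cytosolic ribosomal protein promoters held among genes without a neighbouring TSS (ratio of median signals 3.11, 29 against 1927 genes, permutation p = 0.0001, the smallest possible) and against genes in the same of 5 bins of GC content (2.87, permutation p = 0.0001), which argues against added signal from neighbours and against GC content as the whole cause. Recovery of every highly transcribed locus whatever its polymerase would have given peaks at tRNA genes, and 0 of 258 tRNA genes away from protein-coding TSSs had one, although 67 had some summit in the full list. Reads lost to repeated copies do not account for this where flanks are unique, since 0 of 230 had one among those with at least 90% of the 36-mers in the 300 bp on each side found once in the genome (upper bound 1.59%), although the read length was not given in the sources used here. Away from protein-coding TSSs 2 of 29 snRNA genes, snRNA:U1:95Ca and snRNA:7SKa, had a peak, so this argument covers tRNA genes alone. A TCT initiator was found at 50 of the 85 bound ribosomal protein genes. It went with a signal ratio of 1.09 in 52 other bound genes (bootstrap 95% interval 0.912 to 1.47). In those genes this leaves a modest effect open and excludes one of 2.87. Whether it adds to the ribosomal ratio cannot be told, since ribosomal protein genes with and without it were not compared. Recovery of highly transcribed protein-coding genes by any GFP fusion protein stays open, since no unrelated fusion was analysed here, and no biological explanation was tested.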

How the results depend on the processing

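The alternatives of merged summits, protein-coding TSSs alone, GC stratification, the nearest TSS alone and TSS-centred motif windows, and all alternatives for offsets and list signals, were chosen after the data were seen. Of all values recomputed, 617 kept direction and call, 22 lost a call, 7 gained one, 13 moved and 8 reversed, and the cause was not tested except where the setting itself removes genes or peaks. The stricter threshold left 3207 summits by construction and 27.4% of genes with a promoter peak. That share was 38.6% with a 250 bp window, 45.3% with 1000 bp, 36.01% with the nearest TSS alone and 41.7% to 43.3% without a replicate. Replicate overlap was 89.9% when 50% of the shorter peak had to be shared, 72.7% for summits within 100 bp and 74.2% for the top 1000 summits. The Spearman correlation was 0.685 in the top peaks and 0.765 for nearest summits. The log2 odds ratio of X against autosomes was 0.12 with a 250 bp window, -0.13 under the stricter threshold and 0.13 to 0.16 without a replicate. Lists with fewer peaks numbered 5 among genes without a neighbouring TSS. In that set 1956 of 7933 genes had a promoter peak, against 5889 of 13834 in all, so a low share stood out less. Motifs past the threshold at summits numbered 8 within 50 bp. Summits in 5' UTRs were 2.40% with a 250 bp window, above random. Under the stricter threshold, the promoters counted as without a peak took in those with weaker thresholded peaks. Windows were at summits for promoters with a peak and at the TSS for that group. Log2 odds ratios against that group were -0.15 for DRE, -0.12 for DRE core, -0.64 for Ohler motif 6 and -0.11 for the BEAF core. With TSS-centred windows and all thresholded summits, log2 odds ratios were -0.074 for the CA repeat and 0.16 for the A tract. The promoter share, chromosome 4, short RNA genes and promoter against distal signal kept their calls in every alternative run. At ptc and pros the peak fell to ranks 7053 and 6507 without replicate 3. Depth was not known, so how far it limits weak peaks cannot be said. No paired analysis was possible because the series has 1 group.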

Other observations

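The comparison of strong with weak peaks, the summit offsets by strand and the choice of gene copies were made after the data were seen. Among bound genes, promoters with the strongest peaks differed in sequence from those with the weakest. Motif 1 was within 100 bp of the TSS in 16.3% of the 1472 genes in the top quartile of signal and 9.23% of the 1473 in the bottom quartile (log2 odds ratio 0.94, adjusted exact p = 6.8e-08, Fisher's test over 17 motifs). DRE was in 17.5% against 11.6% (adjusted exact p = 2.3e-05) and the BEAF core in 57.5% against 46.5% (adjusted exact p = 3.8e-08). The E-box went the other way, in 15.1% against 22.3% (adjusted exact p = 2.2e-06), as did the GAGA element, in 16.4% against 22.1% (adjusted exact p = 0.00035). In all, 5 motifs were more frequent at the strongest peaks, 5 less frequent and 7 did not pass.

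Members of the proteasome and oxidative phosphorylation lists without a promoter peak were mostly copies of another member. In the cytosolic ribosomal protein, proteasome and oxidative phosphorylation lists, 37 genes are named as another member plus L, T, R or -like, such as Prosbeta5R1, ND-24L and COX4L, and 6 of them had a promoter peak (16.2%): 2 of 16 in the proteasome list, 1 of 17 in the oxidative phosphorylation list and 3 of 4 in the cytosolic ribosomal protein list. This compares with 245 of 260 other members of these lists and the mitochondrial ribosomal list (94.2%). The naming rule misses copies with other names, so the other members include copies and the counts depend on the rule. Missed copies without a peak include RpL10Aa, RpS10a, RpS5b and COX6AL, and missed copies with a peak were not counted. Of the 31 parent genes, 30 had one. Whether gene copies in general lack peaks stays open. A copy whose promoter matches its parent's could lose reads that map to both, but 1 of the 31 copies without a peak (3.23%) matched its parent at 90 or more of the bases within 50 bp of the TSS. That copy was Prosalpha1R, identical to Prosalpha1 there, and neither gene had a peak, so reads there are uncertain.

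Summits lay downstream of the TSS on both strands. The median offset was 84 bp at plus-strand genes and 77 bp at minus-strand genes, and it was 89 bp at genes with 1 annotated TSS.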
